A study of Rattus norvegicus with 7 samples.

How the data were processed

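Alveolar type 2 cells, the surfactant-producing epithelial cells of the lung alveolus, came from male Sprague Dawley rats fed a Lieber-DeCarli liquid diet for 6 weeks. Ethanol supplied 36% of calories in the treated animals, and the control animals received an isocaloric diet without ethanol. Per the labels, the cells were isolated by immuno-adsorption, RNA was extracted with Trizol, and biotin-labelled RNA was hybridised to an Affymetrix expression array. The design text gives 4 control and 3 treated animals, which are the 4 control and 3 ethanol arrays compared here. The p-values thus measure the spread between animals. In the titles, every control array carries a lower array number than every ethanol array. Diet can therefore not be told apart from any effect that follows this numbering. The array numbers skip a value between the groups, and the ethanol replicate numbers lack the lowest control replicate number. Whether an ethanol array was left out is not given. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.148.

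The deposited table held 1 value for each of 8799 probe sets on each array. From their range, these deposited values were read as log2 expression values. They ran from 1.65 to 12.84, and the array means lay between 4.758 and 4.760, so the arrays were already on a common scale. A natural-log scale was ruled out because the ceiling of a 16-bit scanner is 11.09 on that scale. How the authors summarised probes into probe sets, corrected the background and normalised the arrays is not given in the sources used here. A summarisation that shrinks dim probe sets would understate their differences, and probe sets that share sequence within a gene family can read each other's transcripts. No detection calls were used here.

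The 59 array control probe sets were left out, and the other 8740 were tested. The platform's annotation table gave 1 gene symbol to 7006 of them, several symbols to 308 and none to 1426. Of the probe sets with 1 symbol, 6985 matched the RefSeq gene table of the GRCr8 assembly by Entrez identifier, and 0 symbols changed. No gene was named from a probe set with several symbols. Where a gene had several probe sets, the one with the highest mean over the 7 arrays stood for it, which gave 4736 genes. No genome coordinates were used here.

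Each probe set was tested with limma 3.58.1 in R 4.3.3 (a linear model on the log2 values with the diet group as its term, and empirical Bayes moderation of the variance). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 8740 probe sets, and adjusted p under 0.05 counted as passing. Array-level measures were compared with exact two-sided permutation tests over the 35 ways to divide 7 arrays into 4 and 3. Errors are SD unless SE is written.

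Before the data were examined, 43 gene lists were fixed, 31 for pathways and 12 for cell types that a lung isolate could hold. They covered 683 measured list members and 646 different genes. The 42 lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over those 42. The genes to be named were also set by rule beforehand. They were up to 12 genes in each direction with adjusted p under 0.05, 3 ethanol arrays outside the control range and the greatest difference, filled up to 12 by lowest unadjusted p where fewer passed. The rule also took the first 2 measured members and the up to 3 members with the lowest p of each list, and a set of surfactant, ethanol metabolism, antioxidant, ion transport and junction genes. From the genes this rule allowed, those printed were picked after their values were seen.

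The alternatives were quantile normalization, median centring, 2 filters on dim probe sets, a trended and robust variance prior, array weights, a replicate block, each array left out in turn, no variance moderation, 1 probe set per gene, the mean of a gene's probe sets, camera with an estimated correlation, and fry. The spread of values on each array as a covariate and fry's test for change in either direction were added after seeing the data. The models were tested on simulated data of the same size, 20 simulations with 200 changed probe sets among 8740. They recovered 38.5% of 1.5-fold, 76.0% of 2-fold and 97.5% of 4-fold changes, and 4.64% of the calls were false. The simulated probe sets varied independently of each other, so these rates need not hold for measured probe sets that move together. In simulated lists of independent genes, a shift of 0.5 on the log2 scale was found in 100% of cases, with 0.269% of unshifted lists called. Statmod 1.5.0 served limma, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.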

Results

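Expression in isolated alveolar type 2 cells was compared between 3 ethanol-fed rats and 4 rats on the isocaloric diet, to ask how 6 weeks of ethanol feeding altered their mRNA. Pairs of arrays correlated at 0.929 to 0.983 over all probe sets. The first principal component held 44.2% of the variance and set control 2 apart, at 30.5 against -18.9 to 5.83 for the other arrays. The SD of log2 values on an array was 1.37 ± 0.065 in the controls (n = 4) and 1.39 ± 0.062 with ethanol (n = 3; exact permutation p = 0.657). The 3' minus 5' signal, a measure of RNA integrity, was 0.760 ± 0.175 and 0.826 ± 0.245 for actin (exact permutation p = 0.6), and 0.264 ± 0.074 and 0.320 ± 0.092 for GAPDH (exact permutation p = 0.4).

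Immunoglobulin kappa signal was higher in the cell isolates of the ethanol-fed rats. At adjusted p under 0.05, 13 probe sets differed, and 12 of them rose. Of these 12, 7 were annotated to several kappa light chain variable genes, the antigen-binding parts of antibodies, and were 3.06 to 4.88 times as high as in the controls. The other 5 carried no gene name in the annotation used here. The greatest difference was that of the unnamed probe set M28671_at, which lay at 3.99 to 4.12 in the 4 controls and 7.30 to 8.24 in the 3 ethanol arrays, a 12.4-fold rise (log2 3.63, SE 0.203, adjusted p = 0.00012). Plau, which encodes the urokinase-type plasminogen activator, was the only one of the 13 that fell, from 6.57 ± 0.111 (n = 4) to 5.44 ± 0.027 (n = 3), a log2 difference of -1.13 (SE 0.113, limma with Benjamini-Hochberg adjusted p = 0.0032). Its probe set was X63434_at, and the control values were 2.19 times the ethanol values.

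The kappa probe sets had log2 differences of 1.61 to 2.29 and adjusted p between 0.0032 and 0.00874, and all 3 ethanol arrays lay above all 4 controls in each of the 12. The unnamed U75411cds_g_at rose by 1.55 (SE 0.130, adjusted p = 0.00227). Igkv28, the kappa gene with a probe set of its own (L17078_at), was near the lower end of the array's range, at 2.64 ± 0.168 in the controls and 3.27 ± 0.122 with ethanol, and did not pass (adjusted p = 0.359). The 5 other probe sets with an immunoglobulin symbol, of heavy chain, lambda and surrogate light chain genes, had log2 differences of -0.25 to 0.097 and a lowest adjusted p of 0.967. Those of Ighl11 and the lambda gene Iglc1 were dim, with means of 2.95 and 3.58 over all arrays, so a rise in them could be missed. What the 5 unnamed probe sets that rose read is unknown here, so a rise of other immunoglobulin transcripts is not excluded. Within groups, the 12 probe sets that rose correlated with each other at a mean of 0.797. The 6 measured members of the B and plasma cell list (Cd79b, Cd24, Cxcl13, Cxcr5, Cd37 and Fcer2) had a median log2 difference of -0.082 (camera adjusted p = 0.74). None of them is particular to plasma cells, so this value does not read plasma cells. In limma without variance moderation, 0 of the 13 passed, with 367 probe sets at unadjusted p under 0.05. Without control 1, M18527cds_f_at, a kappa probe set, had an adjusted p of 0.0534, and the others of the 12 still passed.

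**Figure D1:**
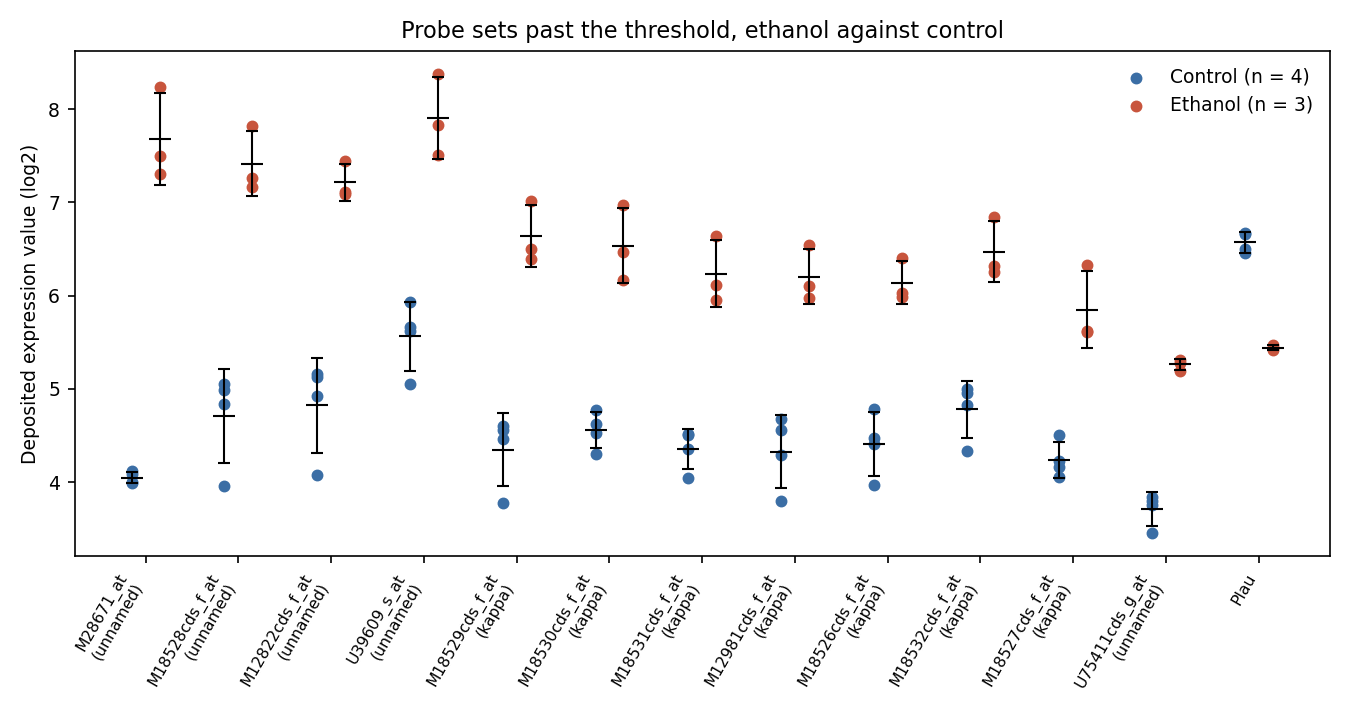
Deposited log2 expression values (vertical axis) of the 13 probe sets past the threshold (horizontal axis) in 4 control (blue) and 3 ethanol (red) arrays. Points are arrays, long ticks are means and bars are SD. M28671_at lies at 3.99 to 4.12 in the controls and at 7.30 to 8.24 with ethanol, and Plau is the only one lower with ethanol.

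At unadjusted p under 0.05 there were 400 probe sets, 4.58% of those tested where chance gives 5%, of which 186 were higher and 214 lower. This share moved with single arrays and with the model: it was 9.03% without control 4, 2.64% without control 3, 2.99% without ethanol 3, 11.8% with array weights and 8.74% with array spread as a covariate. The groups did not overlap in 458 probe sets (5.24%), where chance gives 5.71%.

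Among named genes that did not pass, the lowest p-values on the higher side belonged to Cyp2a3, a cytochrome P450, with a log2 difference of 1.15 (SE 0.185, adjusted p = 0.0777), Sult1a1, a phenol sulfotransferase (1.20, adjusted p = 0.359), Igkv28, and Per2, a circadian clock gene (0.62, adjusted p = 0.403). Sparc, a matrix glycoprotein, followed at 1.01 (adjusted p = 0.403), but its 4 probe sets disagreed, and rc_AA891204_s_at stood at -0.95 (adjusted p = 0.109). Gstm5, a glutathione S-transferase, was at 0.59, Glul, the glutamine synthetase gene, at 0.68, the lipid-binding protein gene Sec14l3 at 1.11, and Cyp2b2, another cytochrome P450, at 0.68, with its other probe set, K01721mRNA_s_at, at 1.86 (adjusted p = 0.292). The serotonin receptor gene Htr1d, the kallikrein gene Klk1 and the integrin gene Itga7 were at 0.52, 0.50 and 0.85, with a lowest probe set of 0.12 for Klk1 and 0.30 for Itga7. The adjusted p of Gstm5, Glul, Sec14l3, Cyp2b2, Htr1d, Klk1 and Itga7 lay between 0.752 and 0.967.

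On the lower side, Fosl1, an AP-1 transcription factor subunit, had a log2 difference of -1.16 (SE 0.203, adjusted p = 0.135), and Tpm4, a tropomyosin, -0.65 (adjusted p = 0.168), while the other Tpm4 probe set stood at 0.072. Eln, which encodes elastin, was at -0.80, the transcription factor gene Ets1 at -0.77, and Msn, which encodes the actin-membrane linker moesin, at -0.72, with adjusted p between 0.403 and 0.468. Gsk3b, a serine-threonine kinase, was at -0.63, the myosin light chain gene Myl6b at -0.60, and Pdlim5 at -0.45. Uck2, Prkar1a and Lcat were at -0.52, -0.46 and -0.42. The adjusted p of Gsk3b, Myl6b, Pdlim5, Uck2, Prkar1a and Lcat ran from 0.735 to 0.967. Second probe sets were closer to 0 for Ets1 (-0.45), Msn (-0.29), Gsk3b (-0.10) and Pdlim5 (-0.30). In the printed probe set of all these genes, higher and lower, the 3 ethanol arrays lay outside the range of the 4 controls. The genes were picked for low p on these same arrays, so this separation largely follows from the choice and adds no support.

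**Figure D2:**
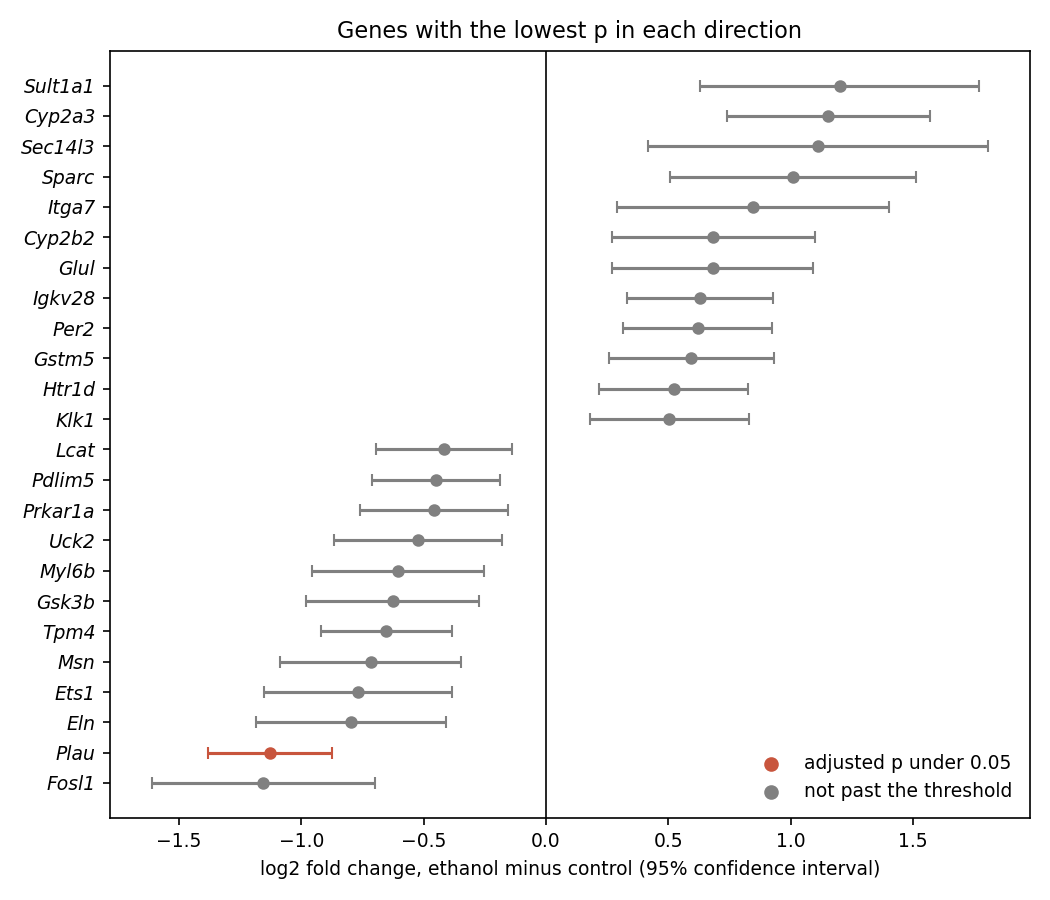
Log2 difference, ethanol minus control (horizontal axis), with its 95% confidence interval, for the 12 named genes with the lowest p in each direction, from 4 control and 3 ethanol arrays. Plau (red), at -1.13, is the one past the threshold, and the gray genes did not pass.

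Transcripts typical of the alveolar type 2 cell did not pass the test in either direction. Sftpc, the surfactant protein C gene, was the highest probe set on all 7 arrays, at 12.80 ± 0.039 in the controls (n = 4) and 12.58 ± 0.186 with ethanol (n = 3), a log2 difference of -0.22 (95% confidence interval -0.49 to 0.055, adjusted p = 0.967). The surfactant protein genes Sftpb, Sftpa1 and Sftpd had differences of 0.12, 0.23 and -0.26, and Nkx2-1, the lung epithelial transcription factor gene, -0.41, with adjusted p of 0.967 to 0.971. The second probe set of Nkx2-1 was at -0.086, of Sftpa1 at 0.049 and of Sftpb at 0.21. With each array left out Sftpc ran from -0.32 to -0.13, Sftpb from 0.0081 to 0.24, Sftpa1 from 0.10 to 0.40, Sftpd from -0.56 to -0.014 and Nkx2-1 from -0.60 to -0.16. The 12 measured type 2 cell markers had a median of -0.023 (camera adjusted p = 0.831), and the 10 surfactant and lamellar body genes -0.046 (adjusted p = 0.752). In limma 0 of either list passed, over all probe sets or adjusted over the list alone, with 1 type 2 marker and 0 surfactant genes at unadjusted p under 0.05. Scgb1a1, the secretory protein of airway club cells, was at 9.28 ± 0.398 and 9.24 ± 0.142, a difference of -0.046 (95% confidence interval -0.51 to 0.42). Markers of macrophages, T and natural killer cells, and endothelium had medians of 0.056, -0.044 and -0.11, with camera adjusted p of 0.604, 0.492 and 0.201.

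**Figure D3:**
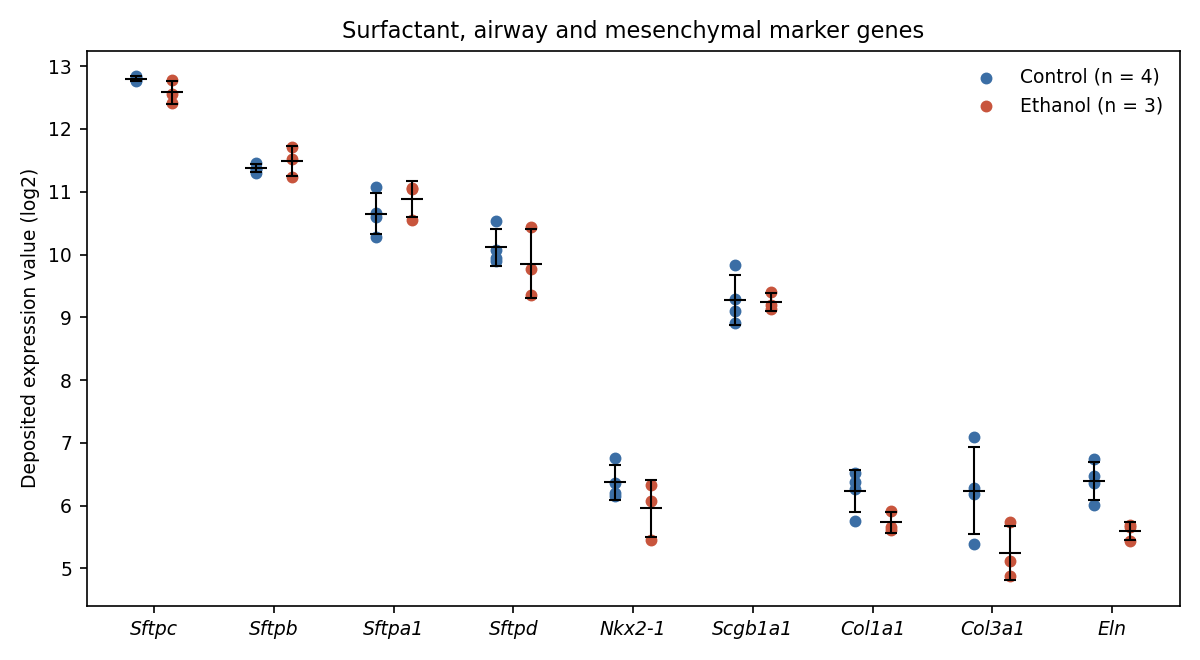
Deposited log2 expression values (vertical axis) of surfactant, airway and mesenchymal marker genes (horizontal axis) in 4 control (blue) and 3 ethanol (red) arrays. Points are arrays, long ticks are means and bars are SD. None of these genes passed the test, and Sftpc lies at 12.80 ± 0.039 in the controls and 12.58 ± 0.186 with ethanol.

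In camera at the preset correlation, 3 gene lists were higher with ethanol (MHC class II, inflammation and heat shock) and 1 was lower (mesenchymal markers). All 4 calls were lost with an estimated correlation, each with an adjusted p = 0.732. Of 10 measured genes in the MHC class II list, 9 were higher, with a mean log2 difference of 0.27 (SE over arrays 0.182, adjusted p = 0.0217, mean 0.17 without ethanol 4). In this list RT1-DMb was at 0.53 with a lowest probe set of 0.12, RT1-Da at 0.57, and Ctss, the cathepsin S gene, at 0.63. Ctss is not itself an MHC class II gene and was also on the macrophage and monocyte list. With each array left out RT1-DMb ran from 0.32 to 0.67, RT1-Da from 0.35 to 0.81 and Ctss from 0.40 to 0.94. Of 25 inflammatory cytokine and NF-kB target genes, 19 were higher, with a mean of 0.19 (SE over arrays 0.305, adjusted p = 0.0337). This mean was 0.41 without control 4, 0.32 without ethanol 3, 0.11 without control 3, 0.077 without ethanol 4 and 0.046 without control 2, and 0.079 with array weights (adjusted p = 0.15). Nfkbia, the NF-kB inhibitor gene, was at 0.67 and the alarmin Il33 at 0.31, while the chemokine gene Cxcl6 was at -0.56. With each array left out these ran from 0.47 to 0.97, 0.20 to 0.37 and -0.68 to -0.34. Il1b and Il1a, which encode interleukin 1, were at 0.25 and 0.13, and in both control 4 stood above the other controls, at 8.08 and 8.66, as it did in Tnf, Ccl3, Ccl4, Ccl2 and Cxcl2, picked after their values were seen. Of 12 heat shock protein genes, 11 were higher, with a mean of 0.19 (SE over arrays 0.169, adjusted p = 0.0337), which was 0.077 without ethanol 4, 0.12 without control 2 and 0.093 with array weights (adjusted p = 0.413). Hspb1 was at 0.43, with probe sets from 0.0054 to 0.98, and Hspa1a at 0.47, from 0.22 to 0.70 with each array left out. Of 21 fibroblast, smooth muscle and mesothelial markers, 17 were lower, with a mean of -0.18 (SE over arrays 0.0692, adjusted p = 0.0337). In this group Eln was at -0.80, and the collagen genes Col3a1, Col1a1 and Col1a2 were at -0.99, -0.50 and -0.62, with a second Col3a1 probe set at -0.50 and the lowest Col1a1 probe set at -0.81. With each array left out Col1a2 ran from -0.86 to -0.41.

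In these 4 lists, 0 genes passed limma over all probe sets. Adjusted over the list alone, 1 gene passed, the mesenchymal marker Eln. At unadjusted p under 0.05 there were 1 MHC class II gene, 5 inflammatory genes, 1 heat shock gene and 5 mesenchymal markers. Apart from leaving single arrays out, the alternatives in camera or fry gave adjusted p of 0.000348 to 0.859 for MHC class II. For inflammation they gave 0.00128 to 0.859, for heat shock 0.000456 to 0.859 and for mesenchymal markers 0.0124 to 0.859. Each lowest value came with the replicate block, which sets control 1 aside. With an estimated correlation 0 lists were at unadjusted p under 0.05, and in fry 0 passed with 2 at unadjusted p under 0.05. The count of lists in camera was 4 (3 higher, 1 lower), 2 (2 higher, 0 lower) after quantile normalization, and 0 with the milder filter on dim probe sets, with 11 at unadjusted p under 0.05. It was 0 without control 2 or without control 3 (8 and 11 at unadjusted p under 0.05), 1 without ethanol 4, 8 without control 1, and 9 without control 4 or without ethanol 2.

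Lists of ethanol handling and redox defence did not pass in camera. Of 15 ethanol and aldehyde metabolism genes 6 were higher and 9 lower, with a median log2 difference of -0.044 (camera adjusted p = 0.786). Cyp2e1, the ethanol-inducible cytochrome P450, was at 0.28 (95% confidence interval -0.029 to 0.59, lowest probe set -0.040), the mitochondrial aldehyde dehydrogenase gene Aldh2 at 0.13, and the alcohol dehydrogenase gene Adh7 at -0.30. Of 30 glutathione and NRF2 target genes 18 were higher and 12 lower (median 0.032, adjusted p = 0.41). The glutamate-cysteine ligase gene Gclc was at 0.32 (0.19 to 0.41 with each array left out), Nfe2l2, which encodes NRF2, at 0.10, and the quinone reductase gene Nqo1 at 0.046, with its other probe set at -0.34. Of 12 other antioxidant enzyme and NADPH oxidase genes 9 were higher, with a median of 0.15 (limma camera adjusted p = 0.107, fry adjusted p = 0.859, both under 0.05 unadjusted). In limma 0 genes of these 3 lists passed, over all probe sets or adjusted over the list alone, with 0 at unadjusted p under 0.05.

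Ion transport and matrix gene lists did not pass in camera either. Of 19 ion and water transport genes 11 were higher (median 0.071, camera adjusted p = 0.191). The epithelial sodium channel genes Scnn1a, Scnn1b and Scnn1g were at 0.50, 0.28 and -0.10, and the sodium pump subunit gene Atp1b1 at 0.39, with a lowest probe set of 0.11. With each array left out Scnn1a ran from 0.32 to 0.80 and Atp1b1 from 0.20 to 0.61. Scnn1b in control 1 stood apart, at 5.75 against 5.36 to 5.42 in the other controls. In limma 0 ion transport genes passed, over all probe sets or adjusted over the list alone, with 1 at unadjusted p under 0.05. Of 24 extracellular matrix genes 16 were lower (median -0.094, adjusted p = 0.421), and adjusted over the list alone 1 was higher, Sparc, and 1 lower, Eln, with 0 past the threshold over all probe sets and 5 at unadjusted p under 0.05. Of 19 renin-angiotensin and TGF-beta signalling genes 11 were higher (median 0.038, adjusted p = 0.831), with Tgfb1 at -0.26 (-0.40 to -0.079 with each array left out), 0 past limma's threshold over all probe sets or adjusted over the list alone, and 1 at unadjusted p under 0.05.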

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

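In the kappa pattern below, the test of B lymphocyte markers was chosen only after the result was seen. The 6 values given first were found by comparing the gap of the outermost control with the range of the 4 controls, in 73 measures of which 6 stood out; chance gives about 1 in 20.

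M18529cds_f_at, a kappa probe set, lay at 3.77 in control 2 and at 4.47 to 4.60 in the other controls. Scnn1b lay at 5.75 in control 1 and at 5.36 to 5.42 in the others. Il1b lay at 8.08 in control 4 against 5.07 to 5.38 in the other controls, and at 6.86, 4.99 and 6.68 in ethanol 2, 3 and 4. Il1a lay at 8.66 in control 4 against 6.40 to 6.62 in the other controls, and at 7.97, 6.15 and 7.42 in ethanol 2, 3 and 4. Tnf lay at 7.78 in control 4 against 4.82 to 5.22 in the other controls, and Ccl4 at 8.17 against 5.78 to 6.15. In ethanol 2, 3 and 4, Tnf lay at 7.09, 5.14 and 6.48 and Ccl4 at 7.27, 5.33 and 6.60. Control 4 was also the highest of the 7 arrays in Ccl3, Ccl2 and Cxcl2. These cytokine genes were picked for this after their values were seen.

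The 12 probe sets that rose kept a median log2 difference of at least 1.74 under quantile normalization, median centring, array weights, the replicate block, array spread as a covariate and each array left out. The 12 were picked from these same arrays for their difference, so this median could hardly fall. It is therefore no independent test of normalization or a single deviating array. Of the 35 splits of the 7 arrays into 4 and 3, 1 split, the real one, gave as many as 13 probe sets and the highest other gave 2. This argues against chance for the count but cannot exclude it, because the splits are few and the 12 probe sets move together. The mean pairwise correlation of the 12 within groups was 0.797, above the 0.127 that marks the 95th percentile of 1000 random sets, so they may not be 12 separate changes. They may be a single transcript family read by many probe sets, or transcripts of a cell type that varied between isolates. The random sets were matched on level only, so this test cannot tell these apart. More B lymphocytes or plasma cells in the ethanol isolates cannot be told apart from a change within other cells. The 6 measured B and plasma cell markers had a median of -0.082, and none is particular to plasma cells. Only 2 passed a brightness bar set after the result was seen (Cd24, which epithelial cells also express, at 6.79 and 6.66, Fcer2 at 5.67 and 5.63 in control and ethanol). Some of the 12 probe sets, such as U75411cds_g_at and M18527cds_f_at, lay below that bar too. The dimmer markers Cd79b, Cd37, Cxcr5 and Cxcl13 had differences of -0.073, -0.091, -0.095 and 0.11. B cells also express MHC class II genes. The MHC class II list, Ctss among its members, had a mean difference of 0.27 (SE over arrays 0.182, 0.17 without ethanol 4, camera adjusted p = 0.732 with an estimated correlation). A loss of lymphocytes in the immuno-adsorption step was not measured here, and an effect of the diet itself stays open.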

How the results depend on the processing

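Array spread as a covariate and fry's test in either direction were chosen after seeing the data. The 13 probe sets numbered 13 to 16 with each array left out, 23 with a replicate block (20 higher, 3 lower, the 13 among them, 8.12% of all at unadjusted p under 0.05), 0 without variance moderation (367 at unadjusted p under 0.05) and 1, Plau, with 1 probe set per gene, since the kappa and unnamed probe sets have no single symbol. Whether equal replicate numbers mark animals handled together is not given in the labels: the deviations of same-numbered arrays correlated at 0.425, 0.0666 and 0.432, and 2 of 3 pairs matched best with their own number, a hint from the data and not the design, so the pairing is unknown; the block also sets control 1 aside, whose number no ethanol array shares. Under the other settings the count was 12 to 19, and the 12 probe sets that rose kept their direction in every setting that tested them. The 4 gene lists numbered 2 with quantile normalization, 0 with the lower filter on dim probe sets (11 at unadjusted p under 0.05), 2 with array weights, 11 with the replicate block, 2 with array spread as a covariate, 0 in camera with estimated correlation (0 unadjusted), 0 in fry (2 unadjusted), 1 in fry in either direction, 9 with the mean of a gene's probe sets, and 0 to 9 with each array left out. Values that reversed, none past the threshold, were Sparc at -0.29 with the mean of its probe sets, Scgb1a1 at 0.11 with array weights and 0.14 with the block, Nfe2l2 at -0.0022 and Nqo1 at -0.011 with array spread, Nqo1 at -0.15 with the mean of its probe sets, Il1b at -0.17 and Il1a at -0.29 with array weights, Il1a at -0.081 with the block, Ccl3 at -0.14 with array weights and Cxcl2 at -0.0071 with array spread. With each array left out, Scgb1a1 ran from -0.17 to 0.14, Aldh2 from -0.070 to 0.30, Nfe2l2 from -0.11 to 0.32, Nqo1 from -0.12 to 0.18, Scnn1g from -0.21 to 0.0095, Il1b from -0.089 to 0.97, Il1a from -0.26 to 0.67, Ccl3 from -0.018 to 0.99, Ccl4 from -0.53 to 0.46, Ccl2 from -0.70 to 0.23 and Cxcl2 from -0.049 to 0.83. Quantile normalization gave Sftpc a difference of 0, because it was the highest on all 7 arrays. Apart from these, the named genes kept their direction, and 13 values of Cyp2a3, Sult1a1, Sec14l3, Fosl1 and Tpm4 passed the threshold under some alternative. Most of the 13 came with array weights, the replicate block or array spread as a covariate. In those settings 8.12% to 11.8% of all probe sets were at unadjusted p under 0.05. Under other alternatives the limma adjusted p reached 0.482 for Fosl1 and 0.974 for the other genes of the 13 values. Except where construction is given, the cause was not tested. Pseudocounts were not run, because the values were on a log scale, and how far dim probe sets lay above background is unknown.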

Other observations

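The test of club cells below was chosen only after the result was seen, as were the covariate of array spread, the comparison of list means with and without it, fry's test in either direction and the choice of the Cyp2b probe sets.

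Ribosomal protein and oxidative phosphorylation genes were mostly higher with ethanol, 28 of 37 and 23 of 34, with median log2 differences of 0.13 and 0.12, and just missed the threshold (camera adjusted p = 0.0607 and 0.0645). Of 21 immediate-early genes 14 were higher (median 0.25, adjusted p = 0.0691), among them Jund, an AP-1 subunit, at 1.72 with a spread of 1.40 between controls. Fosl1, in the same list, lay the other way and was its only gene past the threshold adjusted over the list alone. Of 13 glucocorticoid target genes 9 were higher (median 0.12, adjusted p = 0.0843), and Sult1a1 passed adjusted over the list alone. Of 13 cholesterol synthesis genes 10 were lower (median -0.19, adjusted p = 0.0843). With an estimated correlation these 5 lists had adjusted p between 0.732 and 0.895, and 0 of their genes passed over all probe sets in limma, with 1, 0, 6, 4 and 0 at unadjusted p under 0.05.

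The 4 gene lists past the threshold may reflect differences between arrays other than diet. With array spread as a covariate all 4 kept their direction and 1 its threshold, MHC class II, but the means changed unequally, from 0.19 (SE 0.305) to 0.084 (SE 0.253) for inflammation, 0.19 (SE 0.169) to 0.12 (SE 0.065) for heat shock, 0.27 (SE 0.182) to 0.19 (SE 0.0818) for MHC class II and -0.18 (SE 0.0692) to -0.15 (SE 0.0445) for mesenchymal markers. The criterion written for array spread as the source, at most 1 list keeping both direction and threshold, was thus met. The lists other than inflammation kept 60.5% to 84.8% of their mean, with smaller SE. Array spread thus accounted for part of the variation between arrays in these lists. A lost call alone does not show it as the source of the difference between diets, so the test cannot decide. Array spread was similar with control and ethanol (1.37 and 1.39, exact permutation p = 0.657), so the model could separate it from diet. For inflammation, the mean was smaller than its SE with and without the covariate. Of the 35 splits of the 7 arrays, 25 gave at least 4 lists and the highest other gave 15, so chance cannot be excluded. Such counts may come from a structure of the samples or from list members that correlate beyond the preset 0.01 (estimated 0.0712 to 0.27 in the 4 lists, with which 0 lists passed and 0 were at unadjusted p under 0.05), and an effect of ethanol stays open.

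Of 11 probe sets for the cytochrome P450 2B family, enzymes rich in club cells and liver, 8 were higher with ethanol and in 6 all ethanol arrays lay above all controls (chance separates the groups, either way, in 5.71%), with a median log2 difference of 0.68. Those 6 were annotated, with overlap, to Cyp2b1, Cyp2b2 and Cyp2b15 and may read the same transcripts. Their number thus cannot be weighed against that share as if they were independent. None passed in limma (lowest adjusted p = 0.218, 7 at unadjusted p under 0.05), and the Cyp2b3 probe sets were at -0.23 to -0.044. The smallest median over normalization, covariate, weights, block and left-out arrays was 0.53. The probe sets were picked after their values were seen, so this is no independent test of normalization or a single deviating array. More club cells in the ethanol isolates cannot be told apart from a change within cells: the Cyp2b mean minus Scgb1a1 was higher by 0.62 with ethanol, but the exact permutation p was 0.0857. The 14 measured club and ciliated cell markers, Cyp2b2 among them, had a median of 0.021 (8 higher, 6 lower, camera adjusted p = 0.492). A response of these genes to ethanol is a hypothesis that stays open.

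In fry's test for change in either direction, the list of 9 circadian clock genes was the only one to pass (adjusted p = 0.0144), against 0.492 in camera, 0.878 with an estimated correlation and 0.859 in fry's test of one direction. Without Per2 its p was 0.598, so it rests on that gene. The p of the clock list itself was the lowest of the 35 splits in the real one, rank 1, but the list was singled out from 42 after its value was seen. Of the 35 splits 9 gave at least 1 list in this test and the highest other gave 14, so chance cannot be excluded for the count of lists.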
